A study of Mus musculus with 21 samples.

How the data were processed

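The series holds bulk RNA sequencing of mouse dorsal root ganglia, made from poly-A RNA and read as paired 150-base reads, per the labels. Genotype and treatment were taken from sample titles, because the genotype characteristic gives the Cre line for every sample. The deposited values are raw read counts per gene, in 1 table of 14 libraries and 24524 genes and another of 7 libraries and 24512 genes. The plan assumed that CFA and untreated libraries were in separate tables; in fact the table of 14 holds the CFA libraries and the 6 untreated libraries named LDRG. Reads were trimmed with fastp 0.23.2 and aligned to mm10 with BWA 2.2.1, with SAMtools 1.14 and DESeq2 1.40.2 also used, per the submitters' processing notes. The counting tool is not given in the sources used here. Low counts of 4, 5, 8 and 12 were commoner than some of their neighbours in the table of 14 (4068 values of 4 against 2096 of 3), so that a fragment may have been counted more than once.

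The 24381 genes shared by the tables were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, total 15), TMM normalization, quasi-likelihood F tests and Benjamini-Hochberg adjustment, calling genes at adjusted p under 0.05. Untreated genotypes were compared with name set as a covariate, CFA genotypes among the 8 CFA libraries over all genes of their table, and the interaction and CFA responses in 1 fit of all 21 libraries, where the untreated level is the mean of the name sets. CPM values are counts scaled to TMM-adjusted library sizes. Gene positions came from GENCODE vM21 on mm10, which matched 23573 of the symbols (96.7%). Simulated counts with known changes were run through the same tests.

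A list of 34 gene groups was fixed before the data were examined, and lists with at least 3 measured members were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over lists. Camera with an estimated correlation and fry were the alternatives. Lists for description were chosen after their values were seen, and up to 4 members with the smallest p are given. Named genes are Tmem45b, Mrgprd and, among genes called with a mean of at least 1 CPM in a compared group and a gene name, the 10 largest rises and 10 largest falls; sex-linked genes were left out. Where fewer than 20 passed, the 20 genes with the smallest unadjusted p are given as values only. Genes outside this rule were chosen after their values were seen and are named as such.

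The alternatives chosen before the data were examined were RLE size factors, DESeq2 1.42.0, no filter beyond 1 count, a mean of at least 5 CPM, a replicate block, a sex score covariate, no name set term, each name set alone, code letters as terms, and leaving out each library in turn. A muscle score covariate, untreated libraries coded F only, a spread shared with the LDRG libraries, and removal of genes at 0 to 3 counts in some libraries and 100 or more in others were chosen after the data were seen.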

Results

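RNA was sequenced from dorsal root ganglia of mice, the clusters of sensory nerve cell bodies beside the spinal cord. The mice carried a floxed Tmem45b gene alone (flox) or together with Cre recombinase driven from Mrgprd, a receptor gene that marks a class of nonpeptidergic nociceptors (conditional knockout, cKO). The 21 libraries comprised 6 flox and 7 cKO libraries from untreated mice, and 4 flox and 4 cKO libraries from a CFA model (CFA is not spelled out in the labels; its usual meaning is complete Freund's adjuvant, an emulsion used to induce inflammation). Names divide the untreated libraries into 2 sets. The LDRG set (3 flox, 3 cKO) was deposited in the same table as the CFA libraries, and the con/ko set (3 flox, 4 cKO) in a separate one. Total counts per library ranged from 53.4 M to 72.5 M, with 68.9 M to 71.8 M in the CFA libraries. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, part of which may be technical. No pair of replicates agreed within sampling noise, the chi-square per degree of freedom over 27 pairs ranging from 26.9 to 150.

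The name sets differed more than the genotypes did. The first principal component, with 29.4% of the variance of the 1000 most variable genes, placed the LDRG libraries at -28.4 to -22.7, the CFA libraries at -5.93 to 7.05 and the con/ko libraries at 18.8 to 29.8. Markers of red blood cells followed the same order. Hba-a1, a haemoglobin gene, averaged 11.1 CPM ± 2.80 (SD, n = 3) in LDRG flox, 120 ± 48.8 (n = 4) in CFA flox and 639 ± 219 (n = 3) in con/ko flox libraries. Sex also went with the CFA and LDRG sets: Xist, expressed from the inactive X chromosome, lay at 283 CPM or more in the 8 CFA libraries and at 0.33 CPM or less in the 6 LDRG libraries, while Y-linked genes were the reverse. The con/ko set was mixed. Xist was high in flox_naive libraries 4 and 5 and cKO_naive libraries 4 and 5, and Y-linked genes in flox_naive 6 and cKO_naive 6 and 7. Xist, Hba-a1 and the other genes in this paragraph were chosen after their values were seen.

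The first comparison asked what the Tmem45b deletion in Mrgprd-lineage neurons changes in ganglia of untreated mice. Tmem45b, which encodes a transmembrane protein, fell in cKO ganglia by 1.02 on the log2 scale (SE 0.07, 2.02-fold, adjusted p = 4.8e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the LDRG set its level was 134 CPM ± 10.5 (SD, n = 3) in flox and 66.7 ± 6.46 (n = 3) in cKO libraries, and in the con/ko set 161 ± 16.0 (n = 3) and 79.4 ± 9.05 (n = 4). Each of the 7 untreated cKO libraries (59.7 to 88.2 CPM) lay below each of the 6 untreated flox libraries (124 to 179 CPM). The difference passed the test in the LDRG set alone (-1.01, adjusted p = 0.028) and in the con/ko set alone (-1.02, adjusted p = 0.0122). Two-sided exact permutation tests of this gene gave p = 0.0286 in the con/ko set and p = 0.1 in the LDRG set, each the smallest its design allows. Mrgprd, whose locus drives Cre, did not pass the test (-0.05, SE 0.14, adjusted p = 0.978). Tmem45b lies on chromosome 9 from 31426196 to 31464462 on the minus strand and Mrgprd on chromosome 7 from 145314835 to 145324086 on the plus strand (build mm10). The labels do not say which part of Tmem45b is floxed, and a gene total also counts reads from parts that are not deleted.

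**Figure D1:**
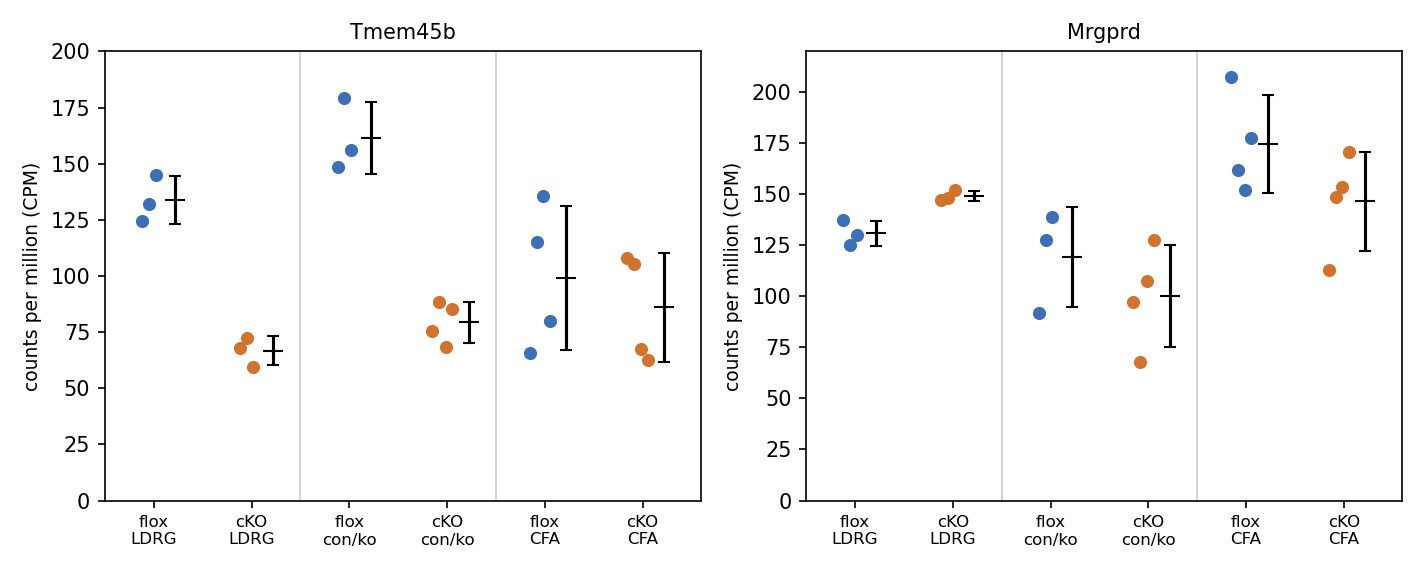
CPM of Tmem45b (left) and Mrgprd (right) in each of the 21 libraries, by genotype and name set; bars give the mean and SD of each group. Untreated cKO libraries (59.7 to 88.2 CPM of Tmem45b) lie below untreated flox libraries (124 to 179 CPM), whereas libraries labelled cKO and flox overlap after CFA.

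Beyond Tmem45b no gene passed the test in untreated ganglia. Of 16706 genes tested by edgeR, 0 rose and 1 fell, 1125 had an unadjusted p under 0.05 where chance gives 835, and DESeq2 called 40 (18 higher and 22 lower in cKO). In simulated counts for these libraries edgeR recovered 62.7% of genes changed 1.5-fold and 80.6% of those changed 2-fold. The simulation held many changed genes and gave 184 calls, which loosens the p threshold after adjustment. These percentages therefore overstate the recovery where few genes change. The genes next in order of p had adjusted p of 0.573 or above. Among them were Rgs5, a marker of pericytes (-0.36, SE 0.07), Csnk2a2, a catalytic subunit of casein kinase 2 (-0.43, SE 0.08), the RNA-binding protein gene Tia1 (-0.93, SE 0.19), Relt, a TNF receptor family member (0.41, SE 0.08), and Slc17a8, the vesicular glutamate transporter VGLUT3 (-0.52, SE 0.12). Log2 differences of the others were -0.18 for Agpat4, -6.68 for Myh7, -0.30 for Tmem200a, -0.16 for Itpkb, 0.18 for Pcca, 0.55 for Wdr72, 0.32 for Ndst4, -0.20 for Vstm5, -1.55 for Synpo2l, 0.30 for Gpank1, -0.74 for Il20rb, -0.45 for Hs3st3b1, 1.55 for Zfp105 and 0.25 for Pctp.

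Gene groups were described by lists fixed before the data were examined. The camera test with its preset correlation between genes called 13 of 33 lists, and with an estimated correlation 0, the lowest adjusted p being 0.26. Lower in cKO by the preset test were C-low-threshold mechanoreceptor genes (adjusted p = 9.2e-10, but adjusted p = 0.26 with an estimated correlation). None of the 6 passed over all genes and all 6 did, as lower, adjusted over the list alone. They included Slc17a8 (-0.52, SE 0.12), the cadherin gene Cdh9 (-0.35, SE 0.08), the secreted protein gene Tafa4 (-0.44, SE 0.13) and Gfra2, a co-receptor for neurturin (-0.16, SE 0.05). The Mrgprd-type neuron list (13 genes, median -0.15) had preset p = 1.1e-06 and adjusted p = 0.26 with an estimated correlation. It had 0 members past the test over all genes or adjusted over the list alone, among them the G protein gene Gna14 (-0.15, SE 0.05) and Plxnc1, a semaphorin receptor (-0.25, SE 0.09). Itch receptors and signalling genes (25 genes, median -0.13, preset p = 0.0253, adjusted p = 0.557 with an estimated correlation) had 0 members past the test over all genes and 0 adjusted over the list alone. The serotonin receptor gene Htr7 stood at 0.17 (SE 0.05) and Il31ra, a subunit of the interleukin-31 receptor, at -0.50 (SE 0.20). Interferon response genes (26 genes, median -0.44, preset p = 1.0e-07, adjusted p = 0.557 with an estimated correlation) likewise had 0 and 0, with Oas2 at -0.54 (SE 0.18) and Ifi44 at -0.78 (SE 0.34). In the con/ko set a C in the library code goes partly with genotype (3 of 4 cKO and 1 of 3 flox libraries), and interferon genes were lower in C libraries (median -0.93, 0 over all genes and 7 adjusted over the list alone, preset p = 1.8e-20, adjusted p = 0.242 with an estimated correlation). By limma's camera with the preset correlation the C-low-threshold mechanoreceptor (adjusted p = 0.0106), Mrgprd-type (adjusted p = 0.00802) and itch lists (adjusted p = 0.00397) were lower in C libraries too. With an estimated correlation camera called 0 lists between C and L libraries, the lowest adjusted p being 0.0919. In the LDRG set alone, which has no such code, the medians of these lists were smaller in size. Tested between the name sets, genotype differences were called for 9 of 33 lists by camera with the preset correlation. With an estimated correlation 0 were called, the lowest adjusted p being 0.522. Within the LDRG set the C-low-threshold mechanoreceptor list had 0 members past the test adjusted over the list alone (median -0.17, preset p = 0.0161, adjusted p = 0.619 with an estimated correlation, Slc17a8 -0.33, Cdh9 -0.23). The con/ko set had 6 (median -0.48, preset p = 2.4e-08, adjusted p = 0.114 with an estimated correlation, Slc17a8 -0.68, Cdh9 -0.45). For the LDRG set the Mrgprd-type list had median -0.08 (limma camera adjusted p = 0.202), the itch list -0.07 (limma camera adjusted p = 0.202, 1 higher and 2 lower adjusted over the list alone) and the interferon list -0.23 (preset p = 0.000881, adjusted p = 0.712 with an estimated correlation).

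Genes of endoplasmic reticulum calcium handling, which the series title names, had 0 of 36 members past the test over all genes and 0 adjusted over the list alone (median -0.04, preset p = 0.0517, adjusted p = 0.344 with an estimated correlation). Their smallest p-values belonged to the chaperone gene Erp44 (-0.12, SE 0.04), the junctophilin gene Jph1 (-0.26, SE 0.12), the calcium buffer gene Casq1 (-1.32, SE 0.64) and the release channel gene Ryr1 (-1.62, SE 0.84). In the con/ko set alone 3 of the 36 fell, namely Atp2a1 (-6.83, SE 0.48), Casq1 (-2.64, SE 0.20) and Ryr1 (-3.33, SE 0.30), which are the forms of these genes used in skeletal muscle, and 7 fell adjusted over the list alone (adjusted p = 0.0273 with an estimated correlation). Over both sets skeletal muscle genes had 0 of 12 members past the test and 2 lower adjusted over the list alone (median -3.47, preset p = 9.3e-15, adjusted p = 0.26 with an estimated correlation). They moved with genotype in the con/ko set: 6 of 12 fell over all genes and 12 adjusted over the list alone (median -6.49, adjusted p = 0.00249 with an estimated correlation). Acta1, skeletal muscle actin, averaged 146 CPM ± 51.7 (SD, n = 3) in con/ko flox and 1.61 ± 0.46 (n = 4) in con/ko cKO libraries. In the LDRG set it ranged from 8.70 to 38.5 CPM in flox libraries, and was 108 CPM in cKO library 1 but 0.50 and 0.56 CPM in the other two.

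The name sets gave different calls. The LDRG set alone called 3 genes by edgeR, Tmem45b, the splicing factor gene Scaf11 (0.67, SE 0.05) and the histone gene H2ac18, at 0 counts in the flox libraries and at least 153-fold higher in cKO against a floor of 3 counts over the group. The con/ko set called 40, 39 of them lower in cKO. The 1 higher was the potassium channel gene Kcnb2, at 168 CPM ± 13.3 (SD, n = 4) against 9.16 ± 1.73 (n = 3) in flox, while the 6 LDRG libraries lay between 8.51 and 10.9 CPM. Kcnb2 was also high in 1 CFA library of each label, flox_CFA library 1 (245 CPM) and cKO_CFA library 4 (299 CPM), the other CFA libraries lying between 9.30 and 10.9 CPM. Across genes, which are not independent replicates, the genotype differences of the name sets had a correlation of -0.08. Leaving out cKO_naive library 1, which held the muscle transcripts, gave 44 calls, and leaving out flox_naive library 1 gave 2. Scaf11, H2ac18, Kcnb2 and the muscle genes were named after their values were seen.

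The second comparison asked the same question in CFA mice, and here the target gene did not separate the labels. Tmem45b measured 65.5, 115, 136 and 80.0 CPM in the libraries labelled flox and 108, 105, 67.7 and 62.6 CPM in those labelled cKO, means of 99.1 ± 32.1 (SD, n = 4) and 86.0 ± 24.2 (n = 4). Its difference was -0.21 (SE 0.26, adjusted p = 0.963 by edgeR; 95% interval -0.78 to 0.37), and a two-sided exact permutation test gave p = 0.543 where the smallest possible is 0.0286. Over fits that left out 1 library it ranged from -0.36 (without flox_CFA library 1) to -0.02 (without flox_CFA library 3). The interval excludes the fall of 1.02 seen in untreated ganglia, its nearest bound being -0.78. The 2 highest libraries labelled cKO exceeded every untreated cKO library, and 2 libraries labelled flox lay at or below the highest untreated cKO library (88.2 CPM). Mrgprd was at -0.25 (SE 0.13, adjusted p = 0.938). Directions of genotype differences in the CFA libraries therefore rest on labels that Tmem45b does not separate.

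No gene passed the test between CFA libraries labelled cKO and flox. Of 16116 genes, edgeR called 0, 799 had an unadjusted p under 0.05 where chance gives 806, and DESeq2 called 18 (12 higher and 6 lower). Simulated changes of 1.5-fold were recovered in 55.2% of genes and of 2-fold in 85.1%. That simulation gave 182 calls, so these percentages too overstate the recovery where few genes change. The smallest p-values, with adjusted p of 0.938, belonged to the cytochrome gene Cyp1b1 (0.81, SE 0.13), the ribosomal protein gene Rps4l (0.52, SE 0.09), the homeobox gene Shox2 (0.48, SE 0.09), Lss, an enzyme of sterol synthesis (-0.35, SE 0.07), the antisense transcript Rab10os (-1.08, SE 0.22) and the Notch effector gene Rbpj (0.79, SE 0.16). Log2 differences of the others were -0.77 for Cipc, -1.03 for Osr1, -0.70 for Sco2, 0.37 for Dnaja1, 0.62 for Rpl37a, 0.44 for Yes1, -0.76 for T2, 0.33 for F2r, 0.30 for Rap1a, 0.57 for Pcdh8, 0.61 for Lox, -1.24 for Luc7l and 0.29 for Rap1b. Leaving out cKO_CFA library 3, flox_CFA library 2 or flox_CFA library 4 gave 1 call each, and leaving out flox_CFA library 1 or 3 gave 2 each.

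In the CFA libraries 7 of 32 lists were called by camera with the preset correlation and 0 with an estimated one. Higher in those labelled cKO were interferon response genes (26 genes, median 0.29, limma camera adjusted p = 6.5e-06), with 0 members past the test over all genes and 0 adjusted over the list alone. Ifit2 was at -0.43 (SE 0.12), Isg15 at 0.84 (SE 0.24) and Mx1 at 1.92 (SE 0.56), and the list had adjusted p = 0.597 with an estimated correlation. Myelinating Schwann cell genes (15 genes, median 0.17, preset p = 1.6e-05, adjusted p = 0.597 with an estimated correlation) also had 0 and 0, with the lipid enzyme genes Ugt8a (0.37, SE 0.13) and Fa2h (0.33, SE 0.13). Large A-fibre neuron genes (14 genes, median 0.16, preset p = 4.4e-05, adjusted p = 0.321 with an estimated correlation) had 0 members past the test over all genes and 1 adjusted over the list alone, the secreted phosphoprotein gene Spp1 (0.31, SE 0.07). Lower were Mrgprd-type neuron genes (13 genes, median -0.14, preset p = 2.1e-05, adjusted p = 0.597 with an estimated correlation), with 0 members past the test over all genes and 0 adjusted over the list alone. They included Wnt2b (-0.24, SE 0.09) and the angiotensin receptor gene Agtr1a (-0.25, SE 0.10). Endoplasmic reticulum calcium handling genes (0 of 36 over all genes, 0 adjusted over the list alone, median 0.03 but mean -0.03, limma camera adjusted p = 0.267, Stim2 at 0.13, SE 0.06) and itch genes (0 of 25, 0 adjusted over the list alone, limma camera adjusted p = 0.114, Il31ra at -0.43, SE 0.17) were not called.

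The third comparison asked whether the genotype difference itself depended on CFA. For Tmem45b the difference was 0.80 higher in CFA than in untreated libraries (SE 0.25, unadjusted p = 0.0042 from the edgeR model, adjusted p = 1 over all genes). Over 16928 genes edgeR called 0, 687 had an unadjusted p under 0.05 where chance gives 846, and DESeq2 called 6 (1 higher and 5 lower). Simulated interactions of 1.5-fold were recovered in 37.3% of genes and of 2-fold in 76.1%. With 152 calls in that simulation, these percentages also overstate the recovery where few genes change. Interferon response genes (26 genes, median 0.74, preset p = 7.0e-12) had 0 members past the test over all genes and 0 adjusted over the list alone, and adjusted p = 0.679 with an estimated correlation. Mx1, an interferon-induced GTPase, was at 2.86 (SE 0.83) and Mx2 at 1.13 (SE 0.38). Endoplasmic reticulum calcium handling genes (36 genes, median 0.07, preset p = 0.017) had 0 and 0 as well, and adjusted p = 0.436 with an estimated correlation, with Erp44 at 0.22 (SE 0.08) and Stim1 at -0.15 (SE 0.07). With the con/ko set alone as untreated, 5 of them were higher adjusted over the list alone (preset p = 3.1e-06, adjusted p = 0.00337 with an estimated correlation), among them Ryr1 (3.08, SE 0.46), Casq1 (2.27, SE 0.48), Srl (0.95, SE 0.22) and Hrc (2.44, SE 0.66). Skeletal muscle genes moved with them: 7 of 12 were higher adjusted over the list alone (median 4.21, preset p = 5.8e-13, adjusted p = 0.226 with an estimated correlation), including Myh4 (6.64, SE 1.74) and Ckm (5.08, SE 1.66). The 1 gene called over all genes was the muscle enzyme gene Pgam2. With LDRG alone 0 calcium handling genes passed adjusted over the list alone (limma camera adjusted p = 0.533). These genes were named after their values were seen. Genes with the smallest p included Synpo2l (2.28, SE 0.51), Tia1 (1.65, SE 0.38), the receptor signalling inhibitor gene Spry4 (0.62, SE 0.14), Togaram2 (0.55, SE 0.13), the kinase gene Yes1 (0.75, SE 0.18) and the nicotinic receptor subunit gene Chrna6 (-0.37, SE 0.10). The others stood at -0.32 for Siae, 0.48 for Ccn4, -1.19 for Sco2, 0.30 for Trib2, 1.10 for Il20rb, -0.39 for Entpd4b, -0.84 for Mroh7, 0.55 for Calcrl, 0.33 for Rap1b, -0.36 for Cbx7, -0.82 for Fmo5, -0.36 for Rasgef1b, 1.18 for Lox and 0.74 for Rep15. The CFA side of this comparison rests on labels that Tmem45b does not separate.

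The remaining comparisons set CFA against untreated libraries of one genotype. Pooled over both name sets, 2273 genes passed the test in flox ganglia (1294 rose, 979 fell) and 3328 in cKO ganglia (1879 rose, 1449 fell). Calls were shared between the genotypes, which use separate libraries: 969 genes rose and 614 fell in both, where independent lists would share 144 and 83.8, and 0 went opposite ways. The same comparison within the table that holds the CFA libraries, against the LDRG set, gave 1129 genes in flox (628 rose, 501 fell) and 421 in cKO (284 rose, 137 fell), with 190 risen and 82 fallen genes in common where independent lists would share 10.8 and 4.15. Against the con/ko set it gave 5000 and 6023. Leaving out flox_CFA library 1, 2 or 4 lowered the pooled flox count to 1281, 1324 or 1248, and leaving out cKO_CFA library 4 lowered the cKO count to 1698. In simulated counts edgeR recovered 80.6% of genes changed 2-fold in flox and 88.1% in cKO. Calls against the LDRG set were set against those against the con/ko set, which share the CFA libraries, over genes tested in both. In flox, of 627 genes risen against LDRG 113 rose (86.2 if independent) and 138 fell (102 if independent) against con/ko, and of 501 fallen 103 fell (81.6) and 84 rose (68.8). In cKO, of 284 risen 60 rose (50.4) and 86 fell (52.5), and of 137 fallen 47 fell (25.3) and 14 rose (24.3). The independent expectation leaves out the shared CFA libraries. With these shared and no effect simulated, fold changes had a correlation across genes, which are not independent replicates, of 0.437 in flox and 0.474 in cKO, against 0.352 and 0.441 observed, and 0 shared calls. The covariance lay the other way, 0.0715 in flox and 0.0877 in cKO observed against 0.0241 and 0.0249 simulated. No label names a batch, so a difference in library making between CFA and LDRG libraries stays open. The libraries also differ in sex. Hoxc10, a gene active in lumbar segments, was at 0 counts in the con/ko libraries flox_naive 4 and cKO_naive 4, 5 and 6. It was at 8.49 CPM or more in each LDRG and CFA library. Comparisons with the con/ko set, and the pooled ones, therefore also set apart libraries that differ in this marker of body position.

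Within that table, transcripts of blood and immune cells rose. Erythroid genes rose in flox (7 of 8 over all genes, 8 adjusted over the list alone, median 3.53, adjusted p = 0.00782 with an estimated correlation) and in cKO (6 of 8, 8 adjusted over the list alone, median 2.73, adjusted p = 0.0151 with an estimated correlation), and preset p-values were 1.5e-29 and 5.2e-23. Hba-a1 was at 3.44 (SE 0.38) in flox and 2.80 (SE 0.36) in cKO, and Alas2, the first enzyme of erythroid haem synthesis, at 3.95 (SE 0.42) and 2.99 (SE 0.40). Of 11 neutrophil genes 9 rose in flox (9 adjusted over the list alone, median 5.14, preset p = 7.4e-22, adjusted p = 0.0132 with an estimated correlation) and 7 in cKO (11 adjusted over the list alone, preset p = 1.8e-20, adjusted p = 0.0151 with an estimated correlation). The cKO median was 3.81 with members at 0 counts in one group set to a floor of 3 counts. S100a9, a calcium-binding protein of neutrophils, was at 4.77 (SE 0.50) and 4.06 (SE 0.49). Fibroblast and meningeal genes rose in 7 of 14 cases in flox (13 adjusted over the list alone, preset p = 4.3e-18, adjusted p = 0.0294 with an estimated correlation) and 8 of 14 in cKO (14 adjusted over the list alone, preset p = 8.3e-19, adjusted p = 0.0289 with an estimated correlation), among them the proteoglycan gene Dcn (1.03, SE 0.14, and 0.81, SE 0.14). Macrophage genes rose in 7 of 18 cases in flox (11 adjusted over the list alone, preset p = 8.3e-09) and 4 in cKO (8 adjusted over the list alone, preset p = 1.5e-07), with adjusted p = 0.0911 and adjusted p = 0.129 with an estimated correlation. Itgam, an integrin of myeloid cells, was at 1.31 (SE 0.21) and 1.43 (SE 0.21). Against the con/ko set the same lists pointed the other way, all 8 erythroid genes falling in both genotypes (medians -2.60 and -3.32).

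**Figure D2:**
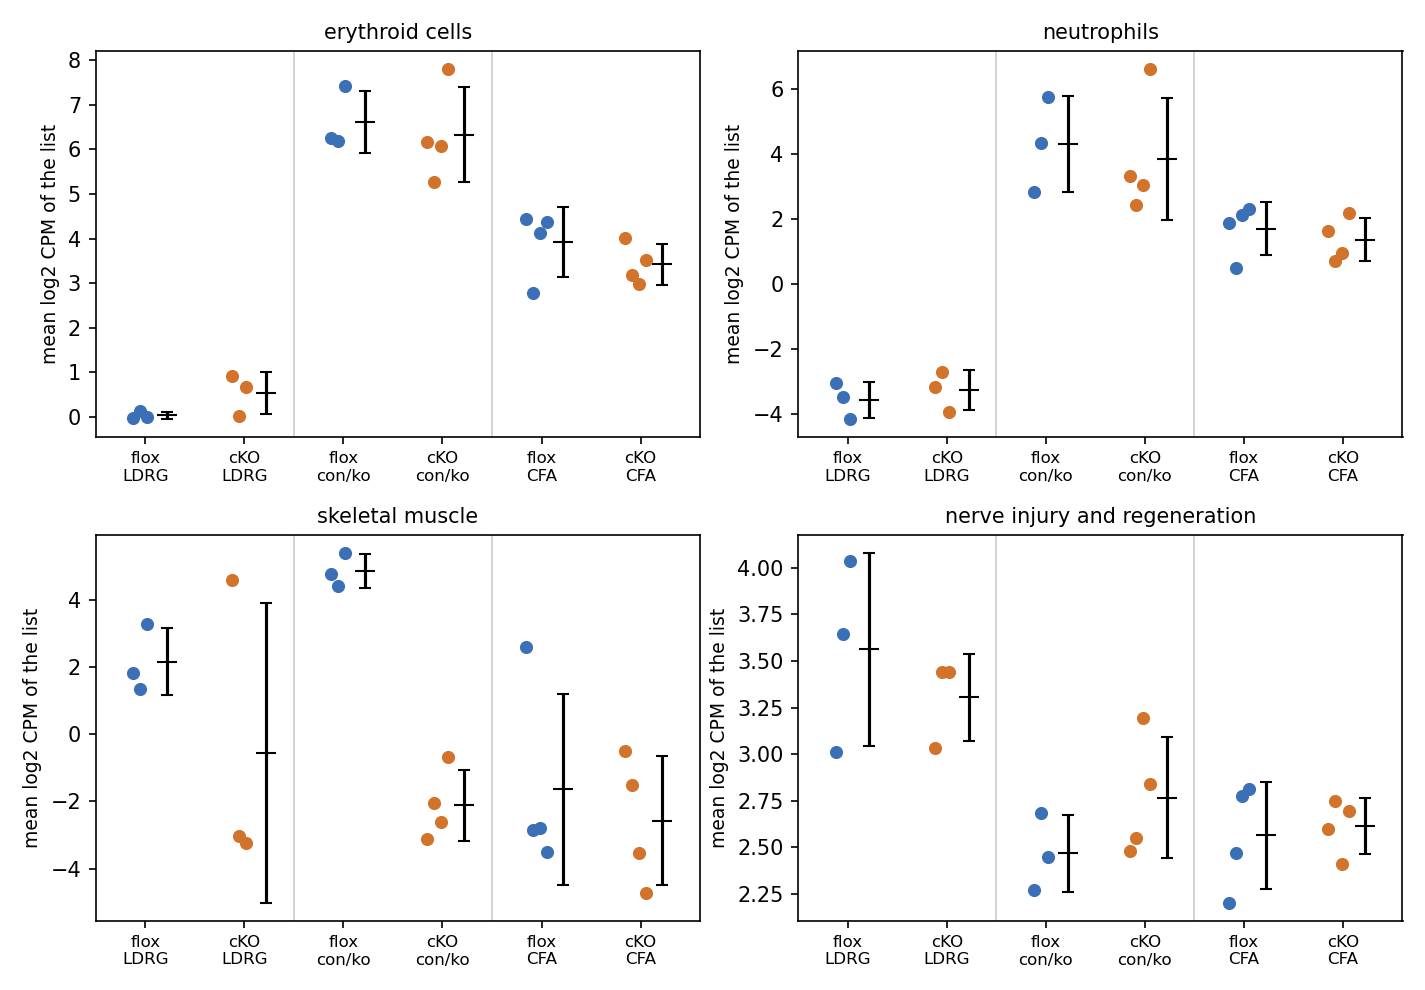
Mean log2 CPM of 4 gene lists in each of the 21 libraries by genotype and name set, with mean and SD per group. Erythroid genes average 0.03 in LDRG flox, 3.92 in CFA flox and 6.62 in con/ko flox libraries, and skeletal muscle genes are high in con/ko flox (4.41 to 5.40) and in LDRG cKO library 1 (4.61).

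In flox, neuropeptide and nerve injury genes were among those lower in CFA than in LDRG libraries. Of 12 peptidergic neuron genes 6 fell in flox (6 adjusted over the list alone, preset p = 7.0e-08, adjusted p = 0.0213 with an estimated correlation), including Adcyap1, which encodes the neuropeptide PACAP (-0.53, SE 0.05), Tac1, the precursor of substance P (-0.48, SE 0.08), and Calca, the precursor of CGRP (-0.53, SE 0.09). In cKO 1 fell, Adcyap1 (-0.24, SE 0.05), with 2 adjusted over the list alone and adjusted p = 0.328 with an estimated correlation. Of 16 nerve injury and regeneration genes 11 fell and 1 rose in flox (12 and 1 adjusted over the list alone, preset p = 2.2e-11, adjusted p = 0.0645 with an estimated correlation), including the injury-induced transcription factor genes Atf3 (-2.10, SE 0.31), Jun (-0.70, SE 0.09) and Sox11 (-0.90, SE 0.13). In cKO 0 fell and 1 rose, Anxa1 (1.56, SE 0.21), with 4 lower and 1 higher adjusted over the list alone and adjusted p = 0.463 with an estimated correlation. The interaction within this table, CFA response in cKO minus that in flox, had 0 members of either list past the test over all genes. Adjusted over the list alone it had 2 peptidergic genes higher (Adcyap1 0.29, SE 0.06; Smr2 0.79, SE 0.20) and 4 injury genes higher, Atf3 (1.37, SE 0.44), Ecel1, Sox11 and Jun. Its preset p-values were 0.000257 for the peptidergic and 1.5e-07 for the injury list, each with adjusted p = 0.453 with an estimated correlation. In untreated LDRG libraries Adcyap1 (-0.22), Smr2 (-0.49) and Sox11 (-0.51) were lower in cKO, past the test adjusted over the list alone. Between CFA libraries their genotype differences were 0.08, 0.32 and 0.20, and those of Atf3 and Jun 0.40 and 0.27. Single libraries differed in level: Atf3 lay at 17.0, 28.6 and 49.4 CPM in LDRG flox libraries, 5.18 to 9.39 CPM in con/ko flox and 6.27 to 8.42 CPM in CFA flox. The mean log2 CPM of the peptidergic list was 6.285 to 6.32 in LDRG flox, 5.86 to 6.09 in CFA flox and 5.42 to 5.88 in con/ko flox libraries. The injury list averaged 3.56, 2.57 and 2.47 in the same order. By these levels, neither list was lower in CFA flox than in con/ko flox libraries. The lists and genes of the comparison with the LDRG set were chosen for description after their values were seen.

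**Figure D3:**
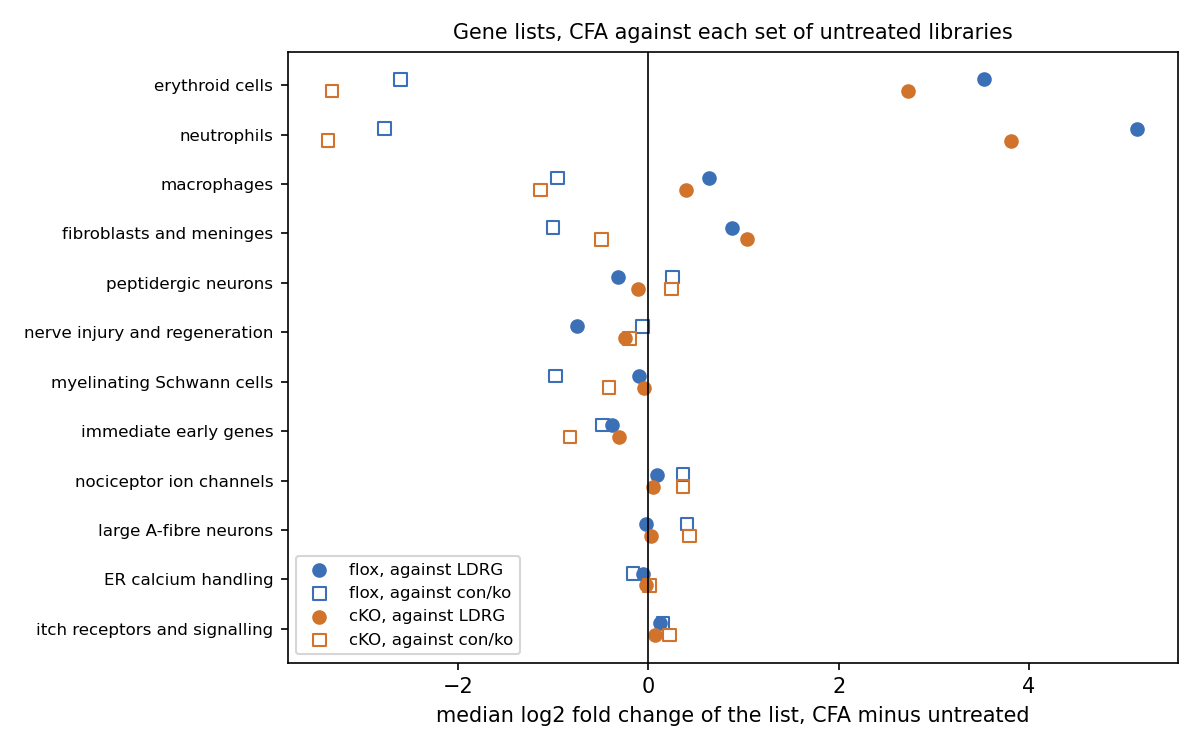
Median log2 fold change of 12 gene lists, CFA minus untreated, against the LDRG set (filled circles) and the con/ko set (open squares), in flox (blue) and cKO (orange); members at 0 counts in one group stand at a floor of 3 counts. Erythroid genes lie at 3.53 and 2.73 against LDRG and at -2.60 and -3.32 against con/ko.

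Pooled over the name sets, more ion channel and A-fibre genes rose than fell, and more immediate early genes fell than rose, in each genotype. None of these lists passed with an estimated correlation. Of 35 nociceptor ion channel genes 8 rose and 1 fell in flox (12 and 1 adjusted over the list alone, median 0.19, preset p = 2.1e-06, adjusted p = 0.587 with an estimated correlation) and 12 rose in cKO (13 adjusted over the list alone, median 0.18, preset p = 0.000416, adjusted p = 0.906 with an estimated correlation). Kcna2, a voltage-gated potassium channel, was at 0.43 (SE 0.06) in flox and 0.35 (SE 0.06) in cKO, and Kcnq3, an M-current subunit, at 0.47 (SE 0.09) and 0.58 (SE 0.09). Against LDRG alone 2 channel genes rose in flox and 0 in cKO. Against con/ko 14 rose and 2 fell in flox and 18 rose and 1 fell in cKO. Kcna2 was then at 0.37 (adjusted p = 0.00634) and 0.26 (adjusted p = 0.0587) against LDRG, and Kcnq3 at 0.22 (adjusted p = 0.208) and 0.32 (adjusted p = 0.103). Of 14 large A-fibre neuron genes 4 rose in flox (7 adjusted over the list alone, preset p = 0.014, adjusted p = 0.587 with an estimated correlation) and 5 in cKO (5 adjusted over the list alone, preset p = 0.00734, adjusted p = 0.625 with an estimated correlation). They included the transcription factor gene Etv1 (0.66, SE 0.10, and 0.82, SE 0.09). Against LDRG alone 1 A-fibre gene rose and 1 fell in flox and 0 rose and 1 fell in cKO. Etv1 was then at 0.29 (adjusted p = 0.159) and 0.45 (adjusted p = 0.0608). Against con/ko 7 and 8 rose. Of 11 immediate early genes 4 fell in flox (6 adjusted over the list alone, preset p = 0.00328, adjusted p = 0.68 with an estimated correlation) and 6 in cKO (6 adjusted over the list alone, preset p = 0.000556, adjusted p = 0.784 with an estimated correlation). They included Egr1 (-1.18, SE 0.26, and -0.88, SE 0.26) and Junb (-0.46, SE 0.13, and -0.50, SE 0.12). Against LDRG alone 2 fell in flox, Egr1 (-0.80, adjusted p = 0.0225) and Junb (-0.51, adjusted p = 0.0168). In cKO 0 fell, these genes being at -0.31 (adjusted p = 0.383) and -0.36 (adjusted p = 0.101). Against con/ko 5 and 9 fell. Another immediate early gene, Zfp36 (-0.73, SE 0.17, and -1.12, SE 0.17), was at 0.05 in flox and -0.34 in cKO against LDRG (adjusted p = 0.892 and 0.244). Of 15 myelinating Schwann cell genes 7 fell in flox (9 adjusted over the list alone, preset p = 2.1e-06, adjusted p = 0.68 with an estimated correlation), such as the peripheral myelin protein gene Pmp22 (-0.80, SE 0.18), and 0 in cKO (0 adjusted over the list alone, preset p = 0.182). The fall in flox lay mainly against con/ko, where 12 fell (median -0.98). Against LDRG 1 rose and 1 fell, Pmp22 (median -0.10, limma camera adjusted p = 0.287; Pmp22 -0.50, adjusted p = 0.0328). In cKO 4 fell against con/ko and 0 against LDRG. The interaction had 0 Schwann cell genes past the test over all genes and 0 adjusted over the list alone (preset p = 0.000164, adjusted p = 0.81 with an estimated correlation).

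Endoplasmic reticulum calcium handling genes went both ways. In flox 4 of 36 rose and 3 fell (5 and 4 adjusted over the list alone, limma camera adjusted p = 0.282), and in cKO 7 rose and 3 fell (8 and 4 adjusted over the list alone, limma camera adjusted p = 0.686). In cKO the median (-0.01) and mean (-0.12) were below 0 while the test pointed up. Atp2a2, the calcium pump of the reticulum, was at 0.27 (SE 0.06) in flox and 0.26 (SE 0.06) in cKO, and Saraf, an inhibitor of store-operated calcium entry, at -0.19 (SE 0.05) and -0.21 (SE 0.05). The other falls in flox were Tmem38b (-0.34, SE 0.09) and the muscle form Casq1 (-2.24, SE 0.67), the latter at -1.01 against LDRG (adjusted p = 0.369) and -3.03 against con/ko (adjusted p = 0.000156). Skeletal muscle genes moved with Casq1: 0 of 12 fell in flox over both sets, and 8 fell against con/ko (11 adjusted over the list alone, median -4.51, preset p = 0.00019, adjusted p = 0.466 with an estimated correlation). The release channel gene Ryr2 was at 0.50 (SE 0.13) in flox and Canx, a chaperone, at 0.26 (SE 0.04) in cKO. Against the LDRG set alone Saraf was called in flox (-0.23, adjusted p = 0.0129) and Canx in cKO (0.20, adjusted p = 0.0338), and Ryr2 in flox (0.28, adjusted p = 0.136) and Atp2a2 were not (0.13, adjusted p = 0.282, and 0.09, adjusted p = 0.508).

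Tmem45b fell in flox from untreated to CFA libraries (-0.56, SE 0.18, adjusted p = 0.0426), and in cKO was at 0.24 (SE 0.17, adjusted p = 0.363). Of the CFA libraries labelled flox 2 (65.5 and 80.0 CPM) lay within the untreated cKO range (59.7 to 88.2 CPM). An exchange of labels could therefore give this fall as well as an effect of CFA. The flox call held against the con/ko set (-0.71, adjusted p = 0.0338) and was lost against the LDRG set (-0.43, adjusted p = 0.301) and in 12 of 21 fits that left out 1 library, namely flox_naive 1 to 6, cKO_naive 1 to 3, and flox_CFA 1, 2 and 4, with adjusted p from 0.0105 to 0.15 over the 21. Mrgprd rose in flox (0.48, SE 0.15, adjusted p = 0.0414) and was at 0.27 (SE 0.15, adjusted p = 0.23) in cKO. Against each name set alone the flox rise was of similar size but did not pass (0.42 against LDRG, adjusted p = 0.0552, and 0.55 against con/ko, adjusted p = 0.0555). In cKO Mrgprd was at -0.03 against LDRG (adjusted p = 0.93) and rose against con/ko (0.55, adjusted p = 0.0326). The interaction was 0.80 (SE 0.25) for Tmem45b and -0.22 (SE 0.22) for Mrgprd, each with adjusted p = 1.

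Few of the largest pooled rises and falls passed against each name set alone, where fewer libraries are compared. In flox the 10 largest rises were Etfbl, Oaz3, Ly6g, Zfp703, Chaer1, Cpeb4, Ugt1a5, S100a7l2, Dlx1as and Mir6236, from 7.28 to 1.39, and the 10 largest falls Ckmt2, Mobp, Bc1, Klhl41, Synpo2l, Casq1, Des, Hspb7, Hif3a and Tpm2, from -4.68 to -1.78. Of these Cpeb4, Mir6236, Synpo2l and Hif3a passed against each name set alone. Among the falls, Klhl41, Synpo2l, Casq1 and Des were also called lower in cKO in the con/ko set, together with skeletal muscle genes. The skeletal muscle list averaged 2.16 log2 CPM in LDRG flox (1.36 to 3.28), 4.86 in con/ko flox (4.41 to 5.40) and -1.64 in CFA flox libraries (-3.50 to 2.60). Whether these falls reflect the level of muscle transcripts in the libraries was not tested. Cpeb4, an RNA-binding regulator of translation, was at 2.21 (SE 0.45), and Hif3a, a hypoxia-inducible factor subunit, at -1.79 (SE 0.38). Dlx1as and Chaer1 (0.07 against LDRG and 4.81 against con/ko for Chaer1) and the neuronal RNA gene Bc1 (-0.19 and -5.45) passed against the con/ko set only and differed in size between the sets. So did Mobp (-1.35 and -6.48), which was also 5.42 higher in con/ko libraries coded C than in those coded L. Ly6g, a neutrophil antigen, was at 0 counts in LDRG libraries and at -1.99 against con/ko. In cKO the rises were Mup11, Etfbl, Igf2, Sp6, Ly6g, Zfp703, Sfrp4, Zfp982, Cpeb4 and Dlx1as, and the falls Tmem170b, Ube2v1, Mobp, Rps23rg1, Bc1, Tymp, Hopxos, Rn7s1, Pdf and Snx12. Mup11, at 0 counts in untreated cKO libraries, was at least 158-fold higher against a floor of 3 counts over the group, and the other rises ran from 7.14 for Etfbl to 1.39 for Dlx1as and the falls from -5.33 for Tmem170b to -1.68 for Snx12. Zfp982, a zinc finger gene, passed against each name set (1.43, SE 0.22). Other changes in cKO were of similar size against LDRG and con/ko, such as Tmem170b (-5.59 and -5.09), Ube2v1 (-4.60 and -4.74), Snx12 (-1.55 and -1.82) and Zfp703 (2.48 and 2.09), without passing against each set. Ly6g passed against each set in opposite directions. It was at least 25.2-fold higher than in LDRG cKO libraries at 0 counts, with a floor of 3 counts over the group (adjusted p = 0.00794). Against con/ko it was at -2.29 (adjusted p = 0.0259). Several of these genes sat at separate levels within a group: Etfbl was at 43.8 and 41.1 CPM in flox_CFA libraries 2 and 4 and at 0.10 and 0.06 CPM in libraries 1 and 3.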

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

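The tests of exchanged labels, of neuron number, of low depth, of batch and of regrouped libraries were chosen only after the results were seen, as was a stricter rule for the test of sex, which left its outcome unchanged.

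Tmem45b overlapped between CFA libraries labelled cKO and flox, and its genotype difference was 0.80 higher on the log2 scale in CFA than in untreated libraries, a difference between groups. A lower share of Mrgprd-type neurons does not account for it. The spread of Tmem45b within CFA groups was 3.10 times that within untreated groups. After the mean of 13 other Mrgprd-type genes was subtracted, it was not reduced, at 4.27 times. No single library decides it, the lowest unadjusted p from the edgeR fits over leave-outs being 0.175. An exchange of labels cannot be told apart from an effect of CFA on Tmem45b. Of the libraries labelled cKO 2 (105 and 108 CPM) lay above every untreated cKO library. Of those labelled flox 2 (65.5 and 80.0 CPM) lay within the untreated cKO range (59.7 to 88.2 CPM), as an exchange would give. The lowest untreated flox library (124 CPM) was reached by 0 libraries labelled cKO, but by only 1 labelled flox, so that this level does not decide. No other gene was called between untreated genotypes over both name sets to place the libraries, and Kcnb2, which separates the genotypes in the con/ko set but not in LDRG, was high in 1 CFA library of each label (245 CPM in flox_CFA library 1 and 299 CPM in cKO_CFA library 4). These libraries also had the lowest Tmem45b of the CFA libraries (65.5 and 62.6 CPM). Kcnb2 was not high in cKO_CFA library 3 and flox_CFA library 4, where Tmem45b was at 67.7 and 80.0 CPM.

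Some genes had 0 to 3 counts in some libraries and 100 or more in others of the same group and name set, such as Etfbl. Of the 78 such genes that were annotated and above 1 CPM, 70.5% overlap another annotated gene, against 61.5% at the upper end of the central 95% of 10000 random lists, which is consistent with reads being given to one or the other of overlapping genes. The median expected count in the low libraries was 196 over 407 values from all such genes. It follows largely from choosing genes at 100 counts or more, and so decides nothing. Total counts ranged only from 53.4 M to 72.5 M, too narrowly to take 100 counts to 3, which argues against low depth. Variants of the mouse background stay open, because the sharing of patterns by near pairs (phi 0.218) lay between the median of random pairings, 0.182, and the upper end of their central 95%, 0.224. The genes also include muscle genes, and no biological explanation was tested.

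The CFA libraries differed from the LDRG libraries in many genes, and also in sex. For the 1069 autosomal genes called in flox, the difference of F from M in con/ko libraries was taken along the direction of the CFA difference. Its median was -0.0724, against 0.43 for CFA, which argues against sex as the cause for these genes as a set. A median does not exclude sex for single genes, of which 30.9% had the same sign. No label names a batch, and that 0 untreated libraries share the CFA name follows from how libraries were named, so that this count decides nothing and a difference in library making stays open.

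Among 140 tests for a library far from the others 10 passed, where chance flags about 1 in 20 groups, or 7. Nociceptor ion channel genes were low in cKO_naive library 5 (gap over range 0.587) and in flox_CFA library 3 (0.875). Endoplasmic reticulum calcium genes were high in cKO_naive library 1 (0.740) and Schwann cell genes in cKO_naive library 5 (0.602). Skeletal muscle genes were high in cKO_naive library 1 (0.673) and in flox_CFA library 1 (0.885). Rostral Hox genes were low in flox_naive library 3 (0.716). In flox_naive library 4 spinal cord genes were high (0.783), caudal Hox genes low (0.640) and Mrgprd low (0.747). For Kcnb2 the genotype difference was 4.06 higher in the con/ko than in the LDRG set (adjusted p = 9.3e-07 by edgeR).

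Libraries were also regrouped into groups of the same sizes. The 1 call between untreated genotypes was reached in 13 of 100 groupings (highest other 4), so that chance is not excluded for this count. The CFA genotype and interaction comparisons have 0 calls, which every grouping reaches (35 of 35, highest other 5, and 60 of 60, highest other 3954), so that these groupings say nothing about chance. The grouping with 3954 put all untreated LDRG libraries in one genotype and all con/ko libraries in the other, and so follows the name sets. The CFA counts of 2273 in flox and 3328 in cKO were each reached in 1 of 60, the real grouping (highest other 3 in each). The other groupings mix CFA with untreated libraries, whereas the real one follows the name set. Any large difference between name sets would give this outcome. These groupings therefore do not decide between CFA and another difference, such as one in library making.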

How the results depend on the processing

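The muscle score, F-coded libraries, a spread shared with LDRG and removal of all-or-none genes were chosen only after the results were seen. Of 5148 values of 199 named gene results under alternatives, most chosen before the data were examined, 4671 stayed the same, 404 were weaker, 63 stronger and 10 reversed. Genes called under neither fit count as the same, 15 changes of sign included. Apart from Tmem45b in untreated ganglia, no named genotype or interaction result was called, so this total says little about those. Of the named CFA results, 11 in flox and 8 in cKO stayed the same with LDRG alone (29 and 28 weaker, 2 and 2 reversed). With a replicate block 2 and 5 did (39 and 32 weaker, 1 and 1 reversed). RLE size factors, other filters, the sex score and removal of all-or-none genes left the counts of called genes on the same side. Single genes depended on the sex score, however. Of the named CFA results, 30 in flox and 24 in cKO stayed the same with it, 12 and 13 were weaker, and 1 in cKO was stronger. The untreated genotype count of 1 became 40 with DESeq2, 3 in the LDRG set, 40 in the con/ko set, 25 with code letters, 4 with the muscle score, and 1 to 44 leaving out 1 library (44 without cKO_naive library 1). The CFA genotype count of 0 became 18 with DESeq2 and 0 to 2 in leave-outs. The interaction count of 0 became 6 with DESeq2 and 1 with the con/ko set, and stayed 0 in leave-outs. CFA in flox, 2273 genes, gave 25 with a replicate block, 1129 with LDRG, 5000 with con/ko, 3839 with F-coded libraries, and 1248 to 2891 in leave-outs. CFA in cKO, 3328 genes, gave 36 with a replicate block, 421 with LDRG, 6023 with con/ko, 5314 with F-coded libraries, and 1698 to 3544 in leave-outs. Replicate numbers do not pair libraries (r across genes, which are not independent replicates, -0.09 to 0.24 untreated and -0.04 to 0.14 CFA; own number best in 1 of 6 and 1 of 4). In the fits of both name sets and of the CFA libraries, lists called were 0 in each comparison with an estimated correlation, against 5 for CFA in flox and 5 in cKO with LDRG alone, and 2 for untreated genotype and 1 for the interaction with con/ko alone; with fry they were 0 for both genotype comparisons and the interaction, 4 for CFA in flox and 3 in cKO. Reversed values were Zfp703 with a replicate block (-0.0759 flox, -0.0276 cKO), Dlx1as (-0.18 flox, -0.47 cKO), Zfp36 (0.0481 flox) and Tymp (0.15 cKO) against LDRG, and Ly6g against con/ko (-1.99 flox, -2.29 cKO) and F-coded libraries (-0.9996 flox, -1.10 cKO); the cause was not tested.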

Other observations

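Hox genes, which mark position along the body axis, differed within the con/ko set. Libraries whose code has a C (flox_naive 4 and cKO_naive 4, 5 and 6) and those with an L (flox_naive 5 and 6 and cKO_naive 7) differed in caudal Hox genes, which are active in lumbar segments: Hoxc10 was at 0 counts in each C library and at 9.05, 9.64 and 10.4 CPM in the L libraries, and Hoxa9 at 0.46 to 1.09 CPM against 42.7 to 48.8 CPM. In a fit of the 7 libraries with genotype and both code letters, edgeR called 14 genes (4 higher and 10 lower in C). Of 10 caudal Hox genes 3 fell, Hoxa9 (-6.12, SE 0.35), Hoxc9 (-5.42, SE 0.40) and Hoxa10 (-8.26, SE 0.74), and all 10 were lower adjusted over the list alone (preset p = 1.3e-77, adjusted p = 0.0919 with an estimated correlation). The letters are not spelled out in the labels. These genes were chosen after their values were seen.

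Other genes differed with the same letters. The phosphatase regulator gene Ensa (2.15, SE 0.07) and the myelin gene Mobp (5.42, SE 0.29) were higher in C libraries, and the matrix protein gene Thbs1 (-1.14, SE 0.10), the chemokine gene Cxcl9 (-4.83, SE 0.35) and the adhesion gene Vcam1 (-1.61, SE 0.15) lower. Of 13 spinal cord genes 1 rose and 6 were higher adjusted over the list alone (preset p = 6.2e-20, adjusted p = 0.242 with an estimated correlation). Neutrophil genes had 0 of 11 past the test and 11 lower adjusted over the list alone (preset p = 2.3e-25, adjusted p = 0.242 with an estimated correlation).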
